A study of Mus musculus with 6 samples.

How the data were processed

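The samples were tumours that S-180 cells, a mouse sarcoma line, had formed under the skin of BALB/c nude mice, which lack a thymus. The labels put 3 samples in a model group and 3 in a group that had received RGLS. Total RNA was extracted with the EASYspin kit and libraries were made with a SMARTER mRNA-Seq kit, per the labels' protocols. Whether the kit marked the strand of the RNA, and which strand setting was used in counting, is not given in the sources used here. The submitters' processing notes name Bowtie2, HTSeq and the mouse build mm10, without versions or roles.

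The authors deposited 1 table of 20160 rows, each with a gene symbol, and 6 columns, each matched to a sample by its title. No column of any other sample was present. Per the values and the name given by the authors, the unit is TMM-scaled CPM, a read count scaled by an effective library size and not divided by gene length. All values of a column were whole multiples of its smallest value above 0 (100% within a tolerance of 0.001 of a read), so whole reads and effective library sizes were recovered. The 6 columns summed to between 17868 and 22137 CPM, that is 1.79% to 2.21% of a full library, so the authors' library sizes included reads outside these rows. What those reads were is not given in the sources used here. The rows held between 369453 and 458641 reads per library, and 1 read was worth between 0.0390 and 0.0576 CPM, which sets the precision of low values. Intervals given for ratios of reads are exact 95% intervals and cover counting error only. For such a ratio, a group without any read was set to a floor of 3 reads over the group. In the median log2 ratios of rows opposite muscle genes, any group under 3 reads was set to that floor.

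Gene positions came from the GENCODE vM21 annotation of GRCm38, the assembly of mm10. A symbol of 19732 rows was found there, and 428 rows had none. A row was called overlapped when exons of a gene on the opposite strand covered at least 50 of its exonic bases. This held for 6281 rows. Positions are counted from 1.

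The comparison was RGLS against model. The test was limma 3.58.1 (R 4.3.3) on log2(CPM + 1) with an intensity trend, 2-sided, with Benjamini-Hochberg adjustment over the rows tested and a threshold of 0.05. Rows with at least 1 CPM in at least 3 of the 6 libraries were tested, which left 2319. Fold changes from this test are on the log2(CPM + 1) scale, which understates the change of low rows. The design assumed normalized values and was kept, with the count tests as alternatives. The 35 gene lists (5 on the topic of the study, 12 pathways, 15 cell types and 3 technical) were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, which left 7 lists. For every list the CPM of its listed members was also summed per library and compared with a 2-sided exact permutation test. With 3 against 3 libraries its smallest p is 0.1. The test, the lists, most alternatives and the rule for named genes were fixed before the data were examined.

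The rule named, in each direction, up to 12 rows past the threshold with no overlap between the groups, at least 5 CPM in the higher group and no clone-based or predicted symbol, by size of change. It also named the 3 members with the smallest p of each topic list and each called list, and 1 member of a called list against its direction. Other rows that are named were chosen after their values were seen. So were a set of 15 housekeeping genes and the use of opposite-strand overlap.

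Alternatives were other pseudocounts (0.1 and 5), filters, variance priors, scalings and set tests, the replicate number as a block, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and leaving out each library in turn. An estimated correlation for camera and the fry test were run on the lists. Setting every library to the same median within overlapped and other rows, and edgeR with TMM factors from the rows, were added after the data were seen.

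The tests were checked on simulated data with the real means, library sizes and the estimated spread. Of 100 rows changed 2-fold, limma recovered 48 among 2328 rows tested, edgeR 39 and DESeq2 37. Of 100 rows changed 4-fold, they recovered 97, 99 and 96. Among unchanged rows limma called 8, edgeR 6 and DESeq2 7. Of 20 lists of unchanged rows, camera called 0, and it called the 1 shifted list. The simulated rows were drawn independently of each other, so this could not show false list calls that come from correlation between genes. All rows shared 1 dispersion (0.0591), and no class of rows was shifted between the groups. False calls from such a shift could therefore not show either. All 15 pairs of libraries differed by more than sampling noise (chi-square per degree of freedom between 3.14 and 9.04), so none was taken as a duplicate. The labels do not say whether the 3 samples of a group came from separate mice, and p-values then measure only the spread between these samples.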

Results

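The series asked how RGLS changes sarcoma tumours, with glycerophospholipid and fatty acid metabolism as its stated topic. The series title ties RGLS to spores of the medicinal fungus Ganoderma lucidum from which the outer coat had been removed, and the mice received it before the tumour cells. RNA was sequenced from 3 model tumours and 3 RGLS tumours. The recovered reads of the table numbered 374354, 369453 and 387933 in the model libraries and 458641, 439611 and 418102 in the RGLS libraries. The authors' effective library sizes were 17377445, 17683298 and 17524238 for model and 25668458, 22892424 and 21394481 for RGLS. The rows of the table therefore held only about 2% of the library size in each sample.

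The rows with most reads were mostly not those of genes known for high expression. Actb, the cytoplasmic actin, held 18 to 218 reads per library, and Gapdh, a glycolytic enzyme used as a reference, held 10 to 33. Over 15 housekeeping genes, all of which had a row, the median of the mean CPM was 0.978, against 29.6 for the 200 rows with most reads. Of the 194 annotated rows among those 200, exons of a gene on the opposite strand overlapped 190 (97.9%). Over all annotated rows the share was 31.8%, and it was 18.2% among rows with 6 reads or fewer. On the mitochondrial genome, mt-Nd6, the only protein gene encoded on its strand, had 278 CPM ± 45.9 (SD, n = 3) in model, while mt-Co1 on the other strand had 15.99 ± 5.40. As the strand setting is not stated, reads of an overlapped row cannot be assigned to the named gene rather than to the gene opposite it, and the opposite gene is given with each such row below.

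**Figure D1:**
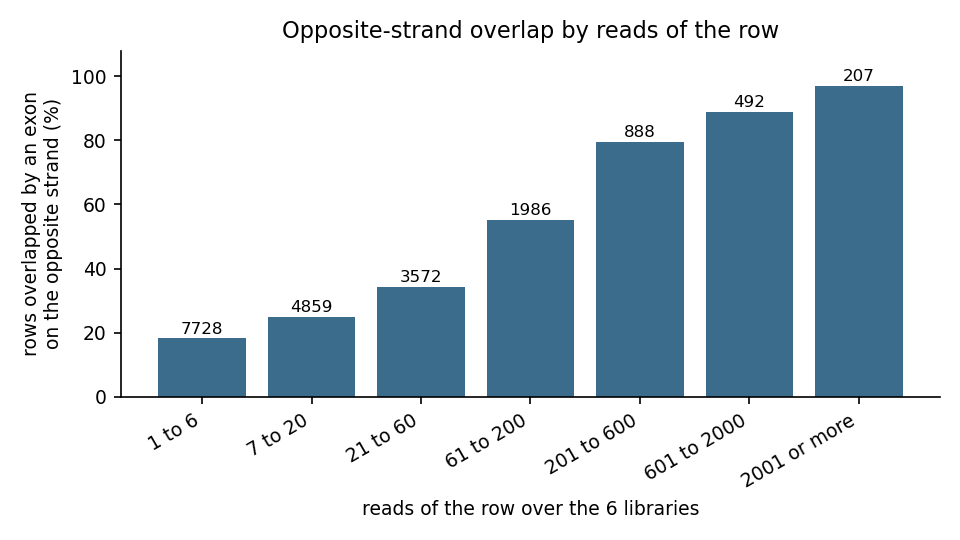
Percent of annotated rows overlapped by at least 50 exonic bases of a gene on the opposite strand, by the reads of the row summed over the 6 libraries, with the number of rows above each bar. The share was 18.2% in the lowest class of 7728 rows and 97.1% in the highest class of 207 rows.

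Among the rows that rose in RGLS tumours were several at skeletal muscle genes. A930016O22Rik, an antisense gene (chromosome 7, 19417466 to 19421417) overlapped over 451 bases by Ckm, the muscle creatine kinase, went from 0.646 CPM ± 0.284 in model to 24.1 ± 9.26 in RGLS (SD, n = 3 each). Its log2 fold change was 3.87 (SE 0.25, limma adjusted p = 7e-08). Rabep2 (chromosome 7, 126428759 to 126449245), overlapped over 763 bases by Atp2a1, the calcium pump of fast muscle fibres, went from 1.29 ± 0.351 to 26.9 ± 12.6 CPM, a log2 fold change of 3.49 (SE 0.28, limma adjusted p = 1.25e-06). Acta1, the skeletal muscle actin, has no gene opposite (chromosome 8, 123891769 to 123894751) and rose from 2 reads over the model libraries to 164 over the RGLS libraries, a ratio of 61.6 after scaling to library size, with a 95% counting interval of 16.8 to 513 (limma adjusted p = 6.11e-05). Ube2c (chromosome 2, 164769898 to 164778822), overlapped over 592 bases by Tnnc2, a troponin of fast muscle, rose from 5 to 123 reads.

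Further low rows rose with them. Des (chromosome 1, 75360329 to 75368579), the intermediate filament protein of muscle, rose from 3 to 118 reads, a ratio of 29.6 with a counting interval of 9.87 to 145, and Gm15179 overlapped it over 220 bases. Nefm (chromosome 14, 68082590 to 68124846), a neurofilament gene overlapped over 1108 bases by Nefl, another neurofilament gene, rose from 0.0951 ± 0.0329 to 2.54 ± 0.376 CPM, and its log2 fold change of 1.69 was next to the 1.68 of Acta1. Ccdc127 (chromosome 13, 74350309 to 74365783), overlapped over 2755 bases by Lrrc14b, rose from 5 to 103 reads. In all 6 of the rows A930016O22Rik, Rabep2, Acta1, Ube2c, Des and Nefm, the 3 RGLS libraries lay above the 3 model libraries. Rabep2 was named by the rule, as was Acta1 as a member of a called list. The other 5 rows were chosen after their values were seen.

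Most of the remaining rows that rose had no gene opposite. mt-Co1 (mitochondrial genome, 5328 to 6872), a subunit of cytochrome c oxidase, rose from 15.99 ± 5.40 to 42.4 ± 16.5 CPM, with a log2 fold change of 1.33 (SE 0.26, limma adjusted p = 0.0167). Ldha (chromosome 7, 46841475 to 46855627), which makes lactate from pyruvate, rose from 0.591 ± 0.386 to 3.21 ± 1.81 CPM. Psap, the precursor of the saposins, and Eif4g1, a translation initiation factor, also rose (both chosen after their values were seen). edgeR did not call them (adjusted p = 0.0544 and 0.0669), while DESeq2 did (0.0425 and 0.0258). Of the 22 rows that rose, 8 are annotated as pseudogenes, whose reads can come from a near-identical parent gene. Reads in rows with no gene opposite made up 13.5% ± 1.03 of the annotated reads in model and 18.6% ± 2.86 in RGLS (SD, n = 3 each, exact p = 0.1, the smallest possible). Setting every library to the same median within overlapped and other rows left mt-Co1 past the threshold (limma adjusted p = 0.0241) and Ldha not (0.0632), with its log2 fold change moving from 1.31 to 1.20. Over all alternatives mt-Co1 lost its call in 8 of 19 (adjusted p between 2.15e-14 and 0.235), among them leaving out model 3, RGLS 1 or RGLS 2. Ldha lost its call in 10 of 18 (adjusted p between 9.3e-08 and 0.282), among them leaving out model 2, model 3, RGLS 1 or RGLS 2.

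All 12 rows that fell were overlapped rows, and camera called none of the lists lower. Gm20481 (chromosome 17, 34969912 to 34972136), overlapped over 564 bases by Hspa1a, which encodes an inducible HSP70, fell from 15.5 ± 1.34 to 4.74 ± 1.05 CPM, a log2 fold change of -1.53 (SE 0.16, limma adjusted p = 4.88e-05). Gm11175 (chromosome 8, 70699162 to 70700080), overlapped over 877 bases by Jund, a member of the AP-1 transcription factors, fell from 99.5 ± 7.18 to 56.1 ± 3.04 CPM. Hspa1a and Jund are both in the technical list of immediate early and heat shock genes. Of the 4 tested rows opposite members of that list, too few for camera, these 2 were called. The rows opposite Jun and Fosl1 had log2 fold changes of -0.45 and -0.12 (limma adjusted p = 0.103 and 0.711). The cause was not tested. Ap3m1 (chromosome 14, 21031442 to 21052508), overlapped over 2090 bases by Vcl, which encodes vinculin of focal adhesions, fell from 207.9 ± 13.0 to 130.7 ± 9.35 CPM, with a log2 fold change of -0.67 (SE 0.11, limma adjusted p = 0.00436). Gm28592, opposite Phlda1, fell from 17.8 ± 0.754 to 10.5 ± 0.781 CPM. Gm15270, opposite Ccn2, a secreted matricellular protein, fell from 9.72 ± 1.17 to 5.48 ± 0.886 CPM. Plet1os, opposite Plet1, fell from 10.7 ± 1.06 to 6.19 ± 0.988 CPM, and Tti2, opposite Mak16, from 64.2 ± 4.23 to 43.3 ± 4.99 CPM. Ap3m1, Plet1os and Tti2 were named by the rule, and the other 4 were chosen after their values were seen. The remaining 5 rows that fell lay opposite Mmp19, Tcim, Gm14048, Rhoa and Got2-ps1.

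**Figure D2:**
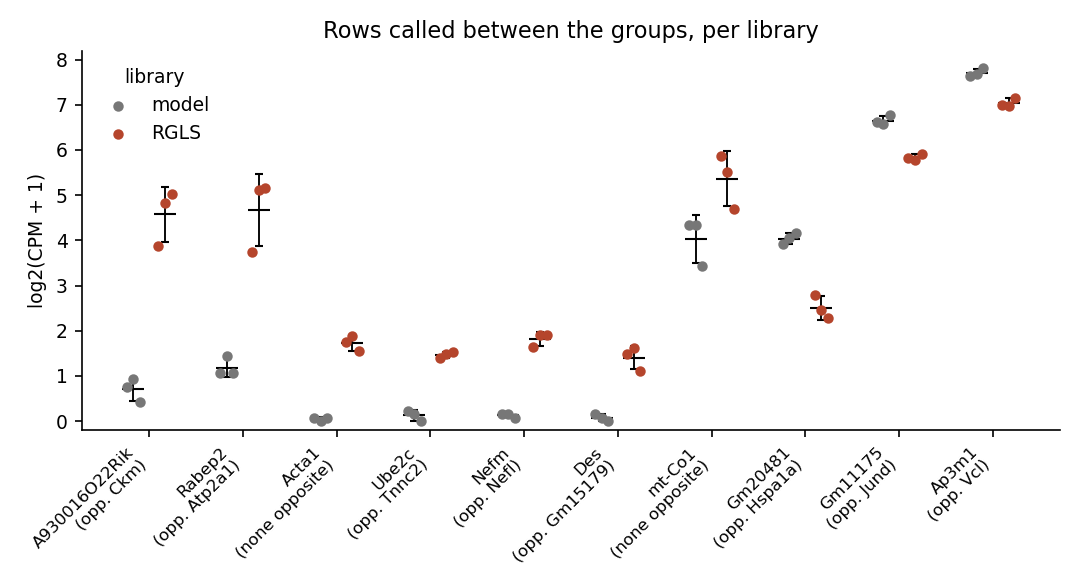
log2(CPM + 1) of 10 rows in each library, with points for the 3 model (grey) and 3 RGLS (red) libraries and bars for mean ± SD. The gene on the opposite strand is in brackets. The RGLS libraries lie above the model libraries in the 7 rows on the left, for example 24.1 against 0.646 CPM in A930016O22Rik, and below them in Gm20481, Gm11175 and Ap3m1.

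Over the 2319 rows tested, limma called 22 rows higher and 12 lower in RGLS, and 21 of these 34 passed 2-fold. At an unadjusted p under 0.05 there were 140 higher and 400 lower. The groups did not overlap in 21 of the 22 higher and all 12 lower calls. Over all rows tested they did not overlap in 618 (26.6%, against 10% by chance for a single row), 105 higher and 513 lower in RGLS. Rows share the scaling of their library, and the summed CPM of all rows was 21524 ± 622 in model and 18871 ± 885 in RGLS (SD, n = 3 each). The 618 rows can therefore not be counted as separate changes. Of the higher calls, 7 were overlapped rows, 14 had no gene opposite and 1 had no symbol in the annotation. All 12 lower calls were overlapped rows. edgeR on the recovered reads called 18 of the 22 and all 12.

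The median log2 fold change over the rows tested was -0.17, so relative to it a change is larger upward and smaller downward. The median was -0.19 over 1799 overlapped rows and 0.01 over 484 rows without a gene opposite. Relative to the median of all rows tested, A930016O22Rik changed by 4.03, Rabep2 by 3.65, Gm20481 by -1.37, Gm11175 by -0.65 and Ap3m1 by -0.50. With the same median set within both classes of rows, 4 of the 12 lower calls stayed past the threshold, which were Gm20481, Gm11175, Ap3m1 and Gm28592. Gm20481 and Gm11175 kept their calls in all 19 alternatives. Ap3m1 lost its call after quantile normalization, where its log2 fold change went from -0.67 to -0.23 (adjusted p = 0.368), and without an intensity trend (0.0770). Gm28592 lost its call in 6 of 19 alternatives (adjusted p between 0.00125 and 0.0902), among them leaving out model 2, model 3, RGLS 1 or RGLS 2. Gm15270 lost its call in 13 of 18, Plet1os in 12 of 18 and Tti2 in 11 of 19. The share of calls that were higher was 64.7%, against 71.4% after a shift to the same median, 77.8% after quantile normalization and 91.7% with edgeR and TMM factors from the rows. It was 45.3% with a robust prior and 4.55% with a stricter filter of 10 CPM. Without 1 library, the higher and lower calls were 36 and 11 (model 1), 12 and 4 (model 2), 7 and 3 (model 3), 7 and 3 (RGLS 1), 7 and 5 (RGLS 2) and 103 and 106 (RGLS 3).

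**Figure D3:**
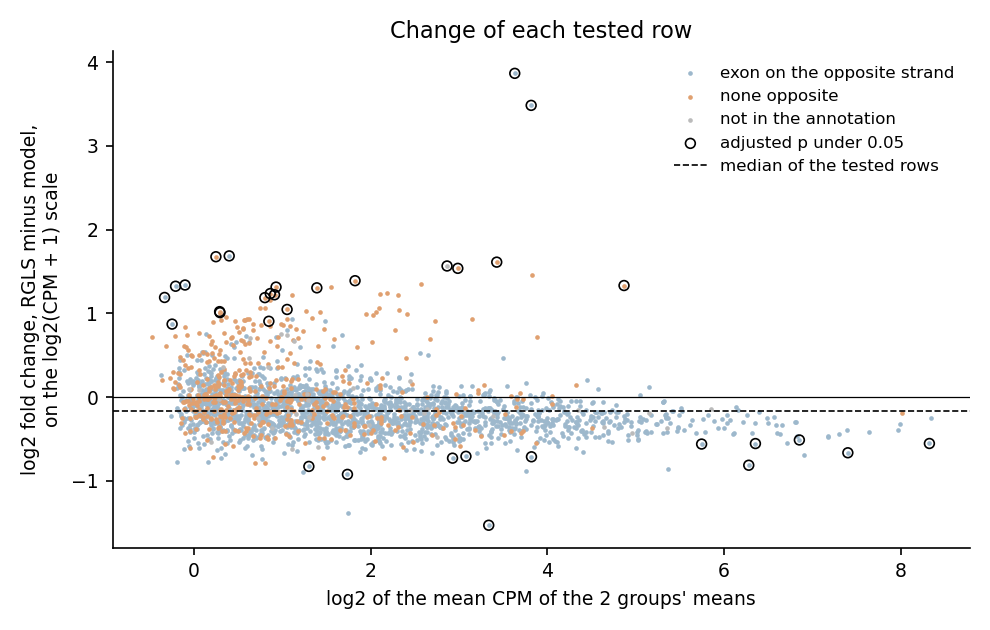
Log2 fold change (RGLS minus model, on the log2(CPM + 1) scale) of the 2319 rows tested against the log2 of their mean CPM, with overlapped rows in blue, rows with no gene opposite in orange, rows not in the annotation in grey and the 34 calls circled. The dashed line is the median of -0.17, and all 12 calls below it are overlapped rows.

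The stated topic, lipid metabolism, was thinly covered. Of the 69 listed genes of glycerophospholipid metabolism 4 reached the tested level, and of 38 genes of fatty acid synthesis, 42 of fatty acid oxidation, 33 of lipid uptake and storage and 24 of eicosanoid metabolism there were 2, 4, 2 and 0. All 12 tested rows were overlapped rows, and limma called none of them in the main test (3 had an unadjusted p under 0.05, and edgeR and DESeq2 called 0 of the 23 and 33 topic rows they tested). Dgkq, a diacylglycerol kinase (opposite Tmem175 and Idua), had 2.26 ± 0.680 CPM in model and 1.14 ± 0.530 in RGLS (limma adjusted p = 0.129). Lpcat3 (opposite Emg1) and Gpat3 (opposite 4930458D05Rik), acyltransferases of phospholipid and glycerolipid synthesis, had log2 fold changes of -0.22 and -0.17. Hacd4 (opposite Focad) and Elovl1 (opposite Cdc20), of fatty acid elongation, had -0.33 and -0.17. Of fatty acid oxidation, Acaa1a, opposite Myd88, had 4.53 ± 0.471 and 2.98 ± 0.700 CPM (adjusted p = 0.143, limma). Acot8, opposite Snx21, had a log2 fold change of -0.39 and Acadvl, opposite Dvl2, of 0.17. Cideb, a lipid droplet protein whose row lies opposite Nop9, had 8.29 ± 0.394 and 5.59 ± 1.99 CPM (limma adjusted p = 0.119, between 0.0129 and 0.415 over its alternatives). It was called lower without RGLS 3, with a log2 fold change of -0.77 against -0.54 and an adjusted p of 0.0129. Lipe, the hormone-sensitive lipase (opposite 4732471J01Rik), had 4.94 ± 1.56 and 3.65 ± 0.531 CPM. These values include the shift of their class, a median log2 fold change of -0.19 over all overlapped rows tested. Relative to the median of all rows tested, Gpat3 had -0.001, Elovl1 -0.005, Lpcat3 -0.05, Lipe -0.16, Hacd4 -0.16 and Acot8 -0.23. On the same measure Acaa1a had -0.32, Cideb -0.37, Dgkq -0.45 and Acadvl 0.33. Adjusted over the list alone, the count was 1 for lipid uptake and storage and 0 for the other 3 lists with tested rows.

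Summed over all listed members, glycerophospholipid metabolism had 15 CPM ± 0.774 in model and 17.7 ± 0.789 in RGLS (SD, n = 3 each, exact p = 0.1, the smallest possible, adjusted 0.35 over 35 lists). All rows with no gene opposite together went from 2856 ± 137 to 3431 ± 381 CPM, and the log2 fold changes of the 4 tested members of the list, all overlapped rows, lay between -0.62 and -0.13. Fatty acid synthesis had 8.96 ± 0.415 and 8.95 ± 1.88 CPM, fatty acid oxidation 13.5 ± 2.18 and 13.2 ± 1.37, lipid uptake and storage 15.6 ± 0.997 and 13.8 ± 2.38, and eicosanoid metabolism 3.55 ± 0.400 and 3.42 ± 0.613. These sums held between 187 and 819 reads per list in the 3 model libraries together, which limits what change could be detected.

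Of the 7 lists with at least 5 tested rows, camera called 3, all higher in RGLS. With an estimated correlation none of the 3 was called (adjusted p = 0.211 with an estimated correlation for each), and fry called 0 of the 7. Mitochondrially encoded genes (7 tested, 1 rose, 5 adjusted over the list alone) had an adjusted p of 2.63e-05 at the preset correlation. mt-Co1 rose, mt-Nd1 had 2.55 ± 0.592 and 9.32 ± 6.20 CPM (limma adjusted p = 0.0503) and mt-Nd2 2.26 ± 0.413 and 6.28 ± 3.23 (adjusted p = 0.0532, limma). Over 18 alternatives mt-Nd1 was called higher in 5 (adjusted p between 1.31e-06 and 0.286) and mt-Nd2 in 6 (between 0.000376 and 0.286), among them edgeR and leaving out RGLS 3 for both. mt-Cytb (4.34 and 8.41 CPM) and mt-Nd4 (2.55 and 4.61) were higher without passing the threshold. mt-Nd5 was nearly level, with 16.79 ± 0.467 and 16.35 ± 5.59 CPM. mt-Nd6 went the other way, with 278 ± 45.9 and 242 ± 32.4 CPM. Summed over its listed members, the list had 322 ± 40.8 and 330 ± 52.3 CPM (exact permutation p = 0.7), most of it from mt-Nd6. Skeletal muscle markers (5 tested, 1 rose, 1 adjusted over the list alone, adjusted p = 0.0109) rested on Acta1. The row of Ckm itself, opposite A930016O22Rik, had 1.999 ± 0.588 and 2.46 ± 0.204 CPM and that of Ttn, the giant sarcomere protein (opposite Gm13938), 1.63 ± 0.341 and 1.47 ± 0.472. Glycolysis and hypoxia (6 tested, 1 rose, 2 adjusted over the list alone, adjusted p = 0.0225) included Ldha, which rose, Pkm, a pyruvate kinase, at 1.28 ± 0.703 and 3.54 ± 1.01 CPM (limma adjusted p = 0.0503), and Car9, a hypoxia-induced carbonic anhydrase (opposite Gm12454), at 1.71 ± 1.04 and 1.01 ± 0.329. Pkm was called higher in 6 of 18 alternatives (adjusted p between 0.000675 and 0.283), among them DESeq2 and leaving out model 1 (0.0331) or RGLS 3 (0.00737). The list of the unfolded protein and integrated stress response (6 tested, 0 past the threshold, 1 adjusted over the list alone) was not called, with an adjusted p of 0.0963 (adjusted p = 0.211 with an estimated correlation). It was called higher in 6 of 20 alternatives (adjusted p between 0.000977 and 0.3 over all), among them edgeR, DESeq2 and leaving out RGLS 3 (0.0196). Hspa5, the main chaperone of the endoplasmic reticulum (no gene opposite, chosen after its values were seen), had 5.63 ± 2.16 and 12.1 ± 5.48 CPM. The glycolysis list was also lost without model 2, without RGLS 1, after quantile normalization and with class medians, and the muscle list without model 2 and with DESeq2. Ldha, Pkm, Acta1 and the mitochondrial rows have no gene opposite, the class of rows whose share of reads was higher in RGLS. Ldha is also among the 15 housekeeping genes, of which all but Tpt1 had a higher mean CPM in RGLS. Actb had 3.44 and 7.21 CPM and Eef2 2.47 and 5.69, so such rises were not limited to glycolysis genes. Rplp0 was nearly level, at 0.248 and 0.277 CPM.

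Cell type markers had few reads. The summed CPM of 8 of the 35 lists was higher in each RGLS library than in each model library, and that of 2 was lower (exact p = 0.1 for each, the smallest possible, adjusted 0.35). Higher besides glycerophospholipid metabolism were skeletal muscle (10.5 ± 1.18 and 15.7 ± 0.652 CPM), Schwann cell and nerve (0.723 ± 0.179 and 3.91 ± 0.465), pericyte and smooth muscle (2.89 ± 0.759 and 5.02 ± 0.767) and fibroblast markers (2.15 ± 0.298 and 2.93 ± 0.0120), extracellular matrix genes (20.1 ± 0.833 and 24.7 ± 3.57), dendritic cell and MHC class II genes (1.82 ± 0.566 and 3.15 ± 0.709) and neutrophil markers (0.133 ± 0.0318 and 0.271 ± 0.0361). Nefm carried most of the nerve sum in RGLS (2.54 CPM, against 0.0951 in model). Des carried most of the difference in the pericyte and smooth muscle sum, with 0.0572 and 1.67 CPM, while Tagln, the other tested member (opposite Gm48529 and Pcsk7), had 1.71 and 1.49. The neutrophil sums rested on 7 and 19 reads. All rows with no gene opposite together rose from 2856 ± 137 to 3431 ± 381 CPM. Small rises such as that of the matrix sum, a ratio of 1.23, cannot be told apart from this shift. Of the 2 tested matrix rows, Mmp11 (opposite Chchd10) had 13.3 and 12.9 CPM and Nid1 (opposite Gm48682) 0.876 and 1.47. Lower were macrophage and monocyte markers (19.0 ± 0.795 and 17.4 ± 1.03) and erythroid and platelet markers (3.94 ± 0.280 and 3.41 ± 0.119). The lower macrophage sum rested on Csf1r (opposite Hmgxb3), with 14.3 and 10.3 CPM, while Apoe, the other tested member, had 1.31 and 3.12. Cell cycle genes had 42.0 ± 3.50 and 43.9 ± 2.52 CPM, but 6 of their 8 tested rows were overlapped rows. Kif20a, opposite Cdc23, alone had 17.97 and 13.45 CPM.

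The libraries were only in part separated by group. On the first principal component, which held 52.5% of the variance, the model libraries had scores of -3.63, -6.06 and -15.6, and the RGLS libraries 12.1, 12.6 and 0.472. Model 3 and RGLS 3 thus lay apart from the other libraries of their groups. Across the rows tested, which are not independent replicates, RGLS 3 correlated at 0.957 with model 2 and 0.955 with model 1, against 0.951 with RGLS 1 and 0.946 with RGLS 2 (Pearson). Rows with no gene opposite were 21.2% of the annotated rows tested and carried 42.0% of the squared loadings of this component. Their share of reads was lowest in model 3 (12.4%) and highest in RGLS 1 (21.3%), with 15.6% in RGLS 3.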

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

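The median within classes of rows and edgeR with TMM from the rows were chosen after seeing the data. Of the 34 calls, 9 were made in every fit that tested them. These were A930016O22Rik, Rabep2, Gm20481 and Gm11175 (20 fits), and Acta1, Nefm, Ube2c, Des and Ccdc127 (19, as they do not reach the stricter filter). All 34 kept their direction wherever tested, but the counts moved with nearly every choice and the cause was not tested, except that other filters change the rows tested. Calls higher in RGLS were 22, and they were 9 with a pseudocount of 0.1, 208 without a filter, 4 with a stricter filter of 10 CPM, 11 without an intensity trend, 34 with a robust prior, 7 after quantile normalization, 10 after a median shift, 35 with edgeR, 37 with DESeq2 and 44 with edgeR and TMM from the rows. Calls lower in RGLS were 12, and in the same order of settings 4, 67, 84, 3, 41, 2 and 4, then 4 with edgeR and TMM from the rows. Calls past 2-fold were 21, and they were 10 with a pseudocount of 0.1, 5 with a pseudocount of 5, 39 without a filter, 5 with the stricter filter, 11 without a trend, 8 after quantile normalization, 10 after a median shift, 39 with edgeR, 38 with DESeq2 and 43 with TMM from the rows. Leaving out each library in turn gave 7 to 103 higher, 3 to 106 lower and 8 to 71 past 2-fold, the highest counts without RGLS 3. With 391 rows, the stricter filter left no list with 5 tested members and gave no count of lists. Lists called were 3, and they were 6 without a filter, 5 with edgeR and with TMM from the rows, 1 to 4 without a library (1 without model 2), and 0 with an estimated correlation and with fry. Added among these were the stress response list without a filter, with edgeR, DESeq2 and TMM from the rows and without RGLS 3, nerve markers, higher, without a filter (adjusted p = 0.0296), and extracellular matrix genes, higher, with edgeR (adjusted p = 0.0341) and TMM from the rows (0.0317).

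The labels state no pairing by replicate number, and the values do not decide whether there was one. Deviations of same-numbered libraries correlated at 0.004, -0.006 and 0.378, the last (model 3 and RGLS 3) being the highest between the groups. Not every library correlated best with its own number (model 1 and RGLS 2 gave 0.331). With the replicate block there were 111 higher, 120 lower and 37 past 2-fold, and 4 lists called, with the stress response list added, and Cideb was called lower (adjusted p = 0.0412).

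No result called in the main test turned its direction. Of those that turned, mt-Nd6 was called lower without a filter (-0.194, adjusted p = 0.000303) and the cell cycle list higher (adjusted p = 0.0429). Without a library, Acadvl ranged from -0.046 (without RGLS 1) to 0.363. Elovl1 ranged from -0.337 to 0.112 (without RGLS 3), and had 0.005 with class medians and 0.007 with TMM from the rows, while Gpat3 had 0.009 with class medians. Ttn ranged from -0.229 to 0.051 (without RGLS 3) and had 0.001 after a median shift, 0.076 with class medians and 0.056 with TMM from the rows, and mt-Nd6 0.222 after quantile normalization. As differences from other rows, cell cycle genes had -0.002 with a pseudocount of 0.1, and -0.078 as the mean fry tests. Cytosolic ribosomal proteins had -0.001 with 0.1, -0.004 without a filter, -0.064 after quantile normalization, -0.051 with edgeR, -0.055 with TMM from the rows, -0.099 with fry and -0.023 to 0.049 without a library. Nuclear genes of oxidative phosphorylation had -0.007 without a filter and -0.130 with DESeq2, and a mean of 0.037 with fry, which read them as lower. The gap between correlations within and between groups was 0.0213, and 0.102 over the 500 most variable rows.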

Other observations

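The test of housekeeping rows was chosen only after the result was seen, as were the tests of muscle rows without a minimum of reads and against rows with no gene opposite, and the 2 settings with class medians and with TMM factors from the rows.

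Read by the gene opposite each row, some muscle rows too low to be tested by limma were also higher in RGLS. Of the 4 given here, edgeR called Gm44646 (adjusted p = 0.000862) and Gm13601 (0.0113), and DESeq2 also Gm49540 (0.0390). Gm44646, opposite Mybpc2, a myosin binding protein of fast muscle, had 1 read over the model libraries and 102 over the RGLS libraries (ratio 76.7, counting interval 13.5 to 3060). Gm13601, opposite Xirp2, had 5 and 78 reads, and Gm49540, opposite Mb, which encodes myoglobin, 2 and 59. Myhas, opposite the myosin heavy chain gene Myh1, had 0 and 29 reads, 7.27-fold higher against a floor of 3 reads over the group, with an exact counting interval that starts at 5.54. The other untested rows opposite muscle genes held at most 6 reads over all libraries. Of them, Apol6 (opposite Mb), Gm31251 (opposite Myh7), Itgad (opposite Cox6a2) and Ccdc63 (opposite Myl2) had more reads in model. Of the extracellular matrix genes, the row opposite Tnc (8030451A03Rik) had 1.37 CPM in model and 0.379 in RGLS and the row opposite Timp3 (Syn3) 17.2 and 9.90. Neither passed the threshold (limma adjusted p = 0.0529 and 0.0976). Both passed it without a filter (0.00393 and 0.00156), but not with class medians (0.165 and 0.201). Camera did not call the list read in this way (6 rows, adjusted p = 0.0578, and adjusted p = 0.776 with an estimated correlation). Of those 6 rows limma called only Gm15270, opposite Ccn2. The rows opposite Fn1, Nid1 and Thbs1 had log2 fold changes of -0.05, -0.31 and -0.39, while read by its own rows the list was higher with edgeR (5 rows, adjusted p = 0.0341).

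The first pattern is that the rows with most reads lie opposite other genes. Missing rows of abundant genes are argued against, since all 15 housekeeping genes have a row at low values, and so are antisense pseudogene copies, since only 6.70% of the annotated top rows have nothing but pseudogenes opposite. A candidate explanation is that reads were counted on the strand opposite to the transcript, so that a row shows mainly its opposite gene. Over 2896 overlapping pairs, the reads of the better-covered gene and of its partner rose together (Spearman rho 0.628 across genes, which are not independent replicates), above the 0.402 to 0.498 of 1000 shuffled pairings, though neighbours with shared expression may give the same. This explanation needs a library that marks strand, which the labels do not state. Counting without regard to strand would leave abundant genes with high rows. The housekeeping rows argue against it, with a highest mean of 14.8 CPM against a median of 29.6 for the 200 top rows. So does mt-Nd6, with 278 CPM in model against at most 16.8 in the listed protein genes on the other mitochondrial strand. No biological explanation was tested.

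The second pattern is that rows with no gene opposite were higher in RGLS relative to overlapped rows. The test of the authors' library sizes decides nothing, since one factor per library moves both classes of rows alike and so fixes the difference of the class medians (105% of its size with TMM factors from the rows). A larger share of reads from the other strand in the RGLS libraries may add to it. Set to class medians, 10 of the 14 higher calls without a gene opposite stayed past the threshold, with a median log2 fold change of 1.15 against 1.27 before, a number between the bounds set in advance, and as the correction sets the class medians equal by construction it cannot be told apart from a change in these transcripts. A biological difference between the groups stays open and untested.

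The third pattern is the rise of rows at skeletal muscle genes. A larger share of reads from the other strand would multiply those reads of all rows by the same factor. The 11 rows opposite muscle genes other than Atp2a1, Tnnc2 and Ckm had a log2 ratio of summed reads of 3.49. All rows with no gene opposite had 0.273, and 10000 lists of them matched on reads had at most 2.34. This argues against a larger share as the only source. The comparison was chosen after the rise of such rows was seen, and 2 rows, Gm44646 and Gm13601, held 102 and 78 of the 284 RGLS reads. Skeletal muscle tissue in the RGLS samples may be the source: without the rows opposite Atp2a1 and Tnnc2, which were seen first, the 5 rows opposite other genes of the list with at least 10 reads over all libraries had a median log2 ratio of 4.03 relative to overlapped rows (highest of 10000 random lists matched on reads 3.28), though only 1 of them, opposite Ckm, had as many reads in model alone. Without that minimum 7 of 12 rows were higher in RGLS, and 4 were at or under the floor of 3 reads in both groups. The median of the 12 was 0.716 (highest random list also 0.716). It fell between 9430073C21Rik and Gm26604, which had 6 and 5 reads in RGLS and 0 in model. Without the row opposite Ckm, the 11 rows summed to 19 reads in model and 284 in RGLS, a ratio of 11.2 (highest random list 3.74). Of the 40 genes of the list, which was fixed before the data were examined, 1 (Car3) is in another list, and the most abundant muscle rows, opposite Ckm and Atp2a1, reached 24.1 and 26.9 CPM. Whether such tissue was taken with the tumours, whether tumours had grown into it or whether tumour cells expressed these genes was not tested, and an effect of RGLS stays open.

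The topic lists were also read through the rows opposite their members, as a hypothesis that their transcripts differ between the groups. Only glycerophospholipid metabolism (20 rows, median log2 fold change -0.11, adjusted p = 0.694) and lipid uptake and storage (5 rows, -0.27) had 5 tested rows, and the smallest camera adjusted p was 0.654. The other 3 lists had under 5 rows, so the test does not cover them. limma called 0 of the 20 glycerophospholipid rows, edgeR 0 and 4 had an unadjusted p under 0.05. With class medians 1 row passed, Abi3 (9.20 and 13.3 CPM, limma adjusted p = 0.0337, against 0.104 without them). It was also called by edgeR with TMM factors from the rows (adjusted p = 0.0430), and it lies opposite Phospho1 of the list but over a longer stretch opposite Zfp652 (2913 against 1708 bases), and also opposite Gngt2.

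There are 10 splits of the 6 libraries into groups of 3, too few for a share under 0.05. The real split gave 34 calls and the highest other 22 (1 of the 10 splits gave as many), 21 calls past 2-fold against 20 (1 of 10), and 3 lists called against 3 (2 of 10). The other split with 22 calls and 3 lists set model 1, RGLS 1 and RGLS 2 against the rest.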
